A study of Mus musculus with 34 samples.

How the data were processed

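The series holds 34 mouse chromatin immunoprecipitation sequencing (ChIP-seq) samples, of which 22 have values and 12 are input samples without a file of their own, so the inputs were not analysed here except through the fold over input printed in the peak files. Each group holds 2 libraries. Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured in blood Ly6C-high monocytes, in repopulating liver macrophages (RLM) taken 24 h after diphtheria toxin, in Kupffer cells (KC, the resident macrophages of the liver), and in bone marrow-derived macrophages (BMDM) with or without the Notch ligand DLL4 for 24 h. Binding of LXR, SMAD4 and RBPJ was measured in Kupffer cells or their nuclei and in BMDM. The BMDM had been cultured for 4 days, except those of the LXR experiment, which had 7 days of culture and 18 h of the LXR agonist GW3965. Groups were taken from the sample titles.

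The deposited H3K27ac values are counts: raw tag counts per region of 2000 bp, in 1 table for monocytes, RLM and Kupffer cells (84647 regions) and 1 table for the 4 BMDM libraries (95038 regions). The region names show that each table merges the peak lists of its own groups, and 55.2% and 50.9% of the regions overlap a neighbour, so a tag can be counted more than once. For each LXR, SMAD4 and RBPJ library the authors deposited a HOMER peak list, which gives per peak a normalized tag count (a signal: tags per 10 M), a findPeaks score and a fold over input (a ratio). Per the file headers, each library was called against 1 input library at a false discovery rate of 0.001, a fold of at least 4 over input and over 10000 bp of local sequence, and a Poisson p of 0.0001. The submitters' processing notes name Bowtie2, HOMER and the build mm10 without tool versions. Gene positions came from a reference table of GRCm38.p6, the assembly that mm10 names. Of the promoter regions, 88.5% and 88.4% lay within 2 kb of an end of the gene that the deposited annotation names, which was checked before the coordinates were joined.

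Depth was 7.37 to 19.5 M tags in regions per library in the first H3K27ac table and 20.2 to 27.2 M in the second. The peak lists rest on 11.1 to 56.3 M tags per library. Per the file headers, the second LXR Kupffer cell library was paired with an input whose name states a NASH diet, while the name of the ChIP library states a control diet. One input library served both the second SMAD4 and the first RBPJ library of Kupffer cell nuclei. The labels do not say whether 2 libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

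Regions were tested with edgeR 4.0.16 (quasi-likelihood test, robust) in R 4.3.3 after TMM normalization and filterByExpr, with Benjamini-Hochberg adjustment. A region or gene was called where the adjusted p was under 0.05 and the fold at least 2, and only those are written as risen or fallen. The 6 libraries of the first table share 1 fit. Fold changes are on the log2 scale with the standard error (SE) of that fit, and levels are CPM over the TMM-scaled total of the tested regions or, for gene-level values, of the tested genes, as mean ± SD of 2 libraries. Where a group held 1 to 3 tags, the ratio of tags is given with its exact binomial 95% interval, which covers counting error only. Gene-level values are sums over the regions whose nearest annotated gene is that gene, within 100 kb. Nearness does not show that a region acts on a gene.

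The 18 gene lists were fixed before the data were examined, as were the tests, the groups, the rule for named genes and most alternatives. They cover Kupffer cell identity, monocytes, macrophages in general, targets of Notch, of TGF-beta and BMP, and of LXR, iron and heme handling, the NF-kB response, the type I interferon response, the cell cycle, class II antigen presentation, and markers of hepatocytes, liver endothelium, stellate cells, neutrophils, lymphocytes, dendritic cells and erythroid or megakaryocyte cells. Of the 30 Kupffer cell identity genes, 7 stand in another list, as do 4 of 24 LXR targets, 3 of 22 TGF-beta and BMP targets and 3 of 15 iron genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 18 lists within a comparison. A list is written as called by camera at the preset correlation, which asks whether its genes differ more than other genes. Fry asks whether they differ at all, gave adjusted p under 0.05 for each list so called, and is printed where it alone did. Member counts are given over all genes tested and adjusted over the list alone.

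The rule for named genes takes, per comparison and direction, the 10 genes with the largest fold change among called regions whose libraries separate fully between the groups and whose level lies above the median of the called regions, 1 region per gene and no predicted gene symbols. It also takes the list genes, and for each factor and cell type the 5 genes nearest to the strongest peaks absent from both lists of the other cell type.

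A peak was taken as reproducible where peaks of both replicates overlapped by at least 1 bp, and as shared where reproducible intervals of 2 cell types did. Peaks of 1 cell type alone overlapped no reproducible interval of the other, but may overlap a peak of 1 replicate. As a chance level, intervals were shifted along the chromosomes 100 times. Counts of peaks are given without a test between cell types. Called regions were compared with tested regions whose adjusted p exceeded 0.05 by two-sided Fisher's exact tests in scipy 1.17.1, adjusted over the 48 tests of the family, and again within 10 strata of mean count (Mantel-Haenszel). Regions of the 2 H3K27ac tables were matched by overlap of at least 1 bp. Because neighbouring regions overlap, intervals and p-values that treat regions as independent are too narrow.

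The overlap code was checked against a brute-force search, and the region test on simulated data with 200 changed regions per table. Simulated on the groups of RLM against monocyte, with 78690 regions fitted, 70.7% of 4-fold and 20.2% of 2-fold changes reached an adjusted p under 0.05. Simulated on DLL4 against untreated BMDM, with 79259 regions fitted, 91% and 67% did. The edgeR fits gave 0 changed regions the wrong sign, and 1 and 3 regions simulated without a change reached that p. A first criterion, recovery of over 80% of 4-fold changes, was not met for RLM against monocyte, and after that result was seen it was replaced by limits on sign, on bias (0.15) and on false calls (20). At this depth and number of libraries, most 2-fold differences between RLM and monocytes were therefore missed in the simulation.

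Alternatives fixed beforehand were other scalings (the size factors of DESeq2, total tags), DESeq2 1.42.0, other count filters, any fold, a fit of 2 groups, a replicate block, each library left out, distal regions, a gene distance of 20 kb, peaks with at least 8-fold over input, equal numbers of peaks per list, and overlap by 50% of the shorter peak. Added after the data were seen were 1 region per locus, libraries thinned to 7 M tags, and strata of level for the overlap of the 2 tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the peaks and the plots.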

Results

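H3K27ac was profiled in 5 groups of mouse myeloid cells with 2 libraries each: blood Ly6C-high monocytes, repopulating liver macrophages (RLM) 24 h after diphtheria toxin in mice whose Clec4f-expressing cells carry the toxin receptor, Kupffer cells, and bone marrow-derived macrophages (BMDM) kept without ligand or with DLL4 for 24 h. Binding of LXR, SMAD4 and RBPJ was profiled in Kupffer cells or Kupffer cell nuclei and in BMDM, again with 2 libraries per group. The H3K27ac libraries held 11.6 and 12.3 M (mega) tags in monocytes, 7.37 and 9.47 M in RLM, and 8.22 and 19.5 M in Kupffer cells. Those of BMDM held 20.2 and 27.2 M untreated and 22.0 and 21.6 M with DLL4. A block of satellite repeats on chromosome 2 took 8.95% and 9.12% of the RLM tags, against 4.67% and 3.95% in monocytes and 2.22% and 1.74% in Kupffer cells. Levels are given as CPM, with the TMM-scaled total of the tested regions of a library as the total and, for values summed by gene, that of the tested genes, and positions are in mm10.

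The first comparison asked which regulatory regions differed between blood monocytes and liver macrophages taken 24 h after toxin. Single regions of C1qb, Abca1 and Spic were among those with far more H3K27ac in RLM than in monocytes. At the promoter of C1qb (chromosome 4, 136885246 to 136887246), which encodes a subunit of complement C1q, the level was 33.6 ± 0.0870 CPM in RLM and 0.454 ± 0.176 in monocytes (mean ± SD, n = 2), a log2 difference of 6.17 (SE 0.35). An intron region of Abca1 (chromosome 4, 53157819 to 53159819), the cholesterol exporter, held 81.4 ± 5.93 CPM against 2.40 ± 0.115. An intron region of Spic (chromosome 10, 88680155 to 88682155), a transcription factor of heme-handling macrophages, held 19.2 ± 0.249 against 0.413 ± 0.000319. In the other direction, an intron region of Atg7 (chromosome 6, 114659481 to 114661481), an enzyme of autophagy, held 4.04 ± 0.889 CPM in RLM and 84.0 ± 10.98 in monocytes. A region in an intron of Gas7 (chromosome 11, 67558738 to 67560738) held 5.06 ± 0.463 and 96.9 ± 7.11.

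Among the other regions with the largest differences, those higher in RLM lay nearest to Tgm2 (log2 difference 5.73, SE 0.31), Rasgef1b (5.69, SE 0.28), Itga9 (5.60, SE 0.32), Sema6d (5.21, SE 0.38), Id2 (5.15, SE 0.34), Lgmn (5.15, SE 0.28) and Snx24 (5.01, SE 0.29). Regions lower in RLM lay nearest to Cyp2ab1 (-4.16, SE 0.29), Susd2 (-3.97, SE 0.33), Fgf1 (-3.93, SE 0.30), Pabpc1l (-3.89, SE 0.35), Zfyve9 (-3.77, SE 0.30), AU019990 (-3.74, SE 0.30), Ankrd55 (-3.72, SE 0.30) and Bfsp1 (-3.71, SE 0.35). For the most changed regions, the naming rule of each H3K27ac comparison required both higher-group libraries to lie above both lower-group libraries.

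Summed over the regions of each gene, 15 of 30 Kupffer cell identity genes were higher in RLM, 1 was lower and 14 did not pass. Their list had adjusted p = 4.31e-17, and adjusted p = 0.0863 with an estimated correlation. Spic differed by 4.15 (SE 0.21) on the log2 scale, Cd38 by 2.68 (SE 0.16), the iron exporter gene Slc40a1 by 2.24 (SE 0.17) and Nr1h3, which encodes LXR alpha, by 2.04 (SE 0.18). The lectin gene Clec4f (0.90, SE 0.23) and the phosphatidylserine receptor gene Timd4 (0.48, SE 0.21), both typical of resident Kupffer cells, did not pass the 2-fold minimum, and Arhgef37 was lower (-1.23, SE 0.20). Of 22 LXR targets 14 were higher and 0 lower, among them Abca1 (2.97, SE 0.16), Abcg1 (2.53, SE 0.16) and Mertk (3.10, SE 0.18). The LXR list had adjusted p = 2.43e-20, and adjusted p = 0.0810 with an estimated correlation. Of 18 macrophage genes 10 were higher, led by C1qb (6.24, SE 0.31), C1qc (4.16, SE 0.36) and C1qa (3.82, SE 0.28). The macrophage list had adjusted p = 1.99e-15, and adjusted p = 0.0810 with an estimated correlation. Of 19 monocyte genes 10 were lower and 0 higher, including Fn1 (-2.49, SE 0.23) and Mcemp1 (-2.34, SE 0.22). The monocyte list had adjusted p = 6.18e-08, and adjusted p = 0.0847 with an estimated correlation.

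Of the lists of signal targets, those of TGF-beta and BMP and of Notch were called upward in RLM, with 6 members of each higher. The TGF-beta and BMP targets had 6 higher and 1 lower of 21, with Id2 (3.36, SE 0.17), Rgs1 (2.72, SE 0.16) and Id3 (1.58, SE 0.15) higher and Pmepa1 (-1.02, SE 0.21) lower. Here adjusted p = 6.91e-06, and adjusted p = 0.0863 with an estimated correlation. The Notch targets had 6 higher and 0 lower of 18, with Hes1, a repressor activated by Notch, at 215 ± 31.8 CPM in RLM and 33.1 ± 13.8 in monocytes. The Notch list had adjusted p = 0.00272, and adjusted p = 0.115 with an estimated correlation. Iron and heme genes had 5 higher of 15, among them Slc48a1 (1.94, SE 0.18) and Blvrb (1.40, SE 0.20). The iron list had adjusted p = 6.22e-08, and adjusted p = 0.181 with an estimated correlation. By camera no list call was made for the NF-kB response (5 higher and 1 lower of 20, adjusted p = 0.115) or class II presentation (3 higher and 1 lower of 12, adjusted p = 0.115). Neither was one made for the interferon response (1 lower of 20, adjusted p = 0.921) or the cell cycle (1 higher and 2 lower of 20, adjusted p = 0.385). The NF-kB list was called without RLM replicate 1 (adjusted p = 0.0300), and the class II list without monocyte replicate 2 (0.00198) or without RLM replicate 2 (0.0192). Fry gave the NF-kB list adjusted p = 0.0423 (upward).

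Markers of other cell types were few in the RLM difference: 1 of 9 measured hepatocyte genes was higher (Ttr, 1.51, SE 0.32, adjusted p of the list 0.625), 1 of 12 endothelial genes (Cldn5, 1.16, SE 0.40, adjusted p 0.695) and 0 of 8 stellate genes (0.921). Neutrophil genes had 1 higher and 1 lower of 13 (adjusted p 0.414), lymphocyte genes 2 lower of 13 (0.921), dendritic cell genes 1 higher and 3 lower of 13 (0.847), and erythroid and megakaryocyte genes 1 higher of 6 (Pf4, 2.78, SE 0.24, adjusted p 0.115). These p-values are by camera. Fry gave adjusted p = 0.0295 for neutrophil (downward) and 0.0225 for erythroid and megakaryocyte genes (upward). The counts adjusted over the list alone were the same, except that 0 endothelial genes passed.

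By the edgeR test, 6942 regions in 4386 separate loci were higher in RLM than in monocytes and 7399 in 4745 loci were lower. The test covered 80982 regions. Of the higher regions 66.8% and of the lower 71.2% lay over 3 kb from a transcription start, against 65.9% of all tested regions. RLM came from a mouse strain that had been given toxin and the monocytes came from blood, so niche, strain and toxin differ together. The labels name the libraries of a group only as separate samples, so all p-values measure the spread between these samples, which may be technical.

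**Figure D1:**
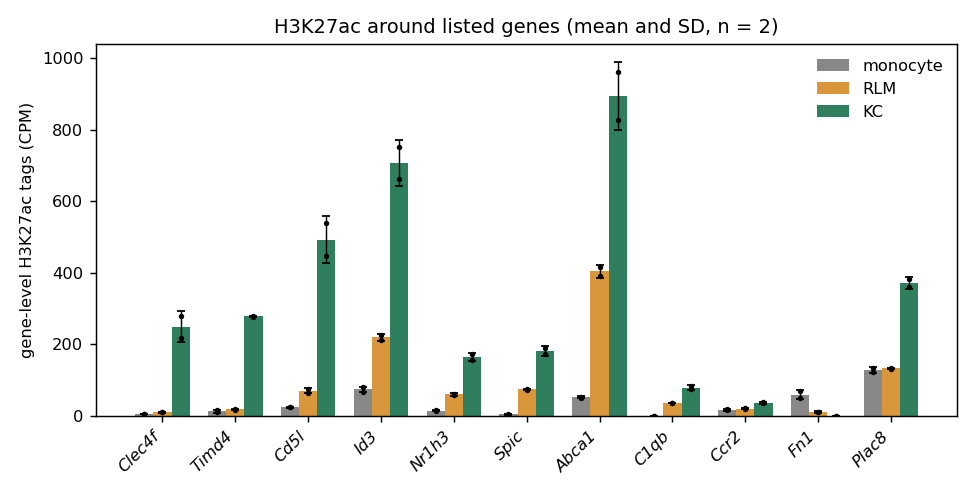
H3K27ac summed over the regions of 11 genes of the fixed lists in monocytes, RLM and Kupffer cells, in CPM (mean and SD of 2 libraries, with each library as a point). Clec4f had 5.39 ± 0.692 CPM in monocytes, 10.0 ± 1.18 in RLM and 249 ± 43.2 in Kupffer cells.

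Resident Kupffer cells were then set against RLM. Kupffer cells had far more H3K27ac at genes that mark them. Summed over its regions, Clec4f was higher by 4.62 (SE 0.21) on the log2 scale, with 249 ± 43.2 CPM in Kupffer cells and 10.0 ± 1.18 in RLM (n = 2), and Timd4 by 3.95 (SE 0.20), with 278 ± 2.01 and 18.0 ± 1.38. An intergenic region 14717 bp from the start of Paqr9 (chromosome 9, 95573534 to 95575534) held 58.4 ± 5.23 CPM against 0.385 ± 0.173. Kupffer cells had almost no tags in the promoter region of the coagulation factor gene F10 (chromosome 8, 13035652 to 13037652), where the ratio of RLM to Kupffer cell tags was 380.3 (95% interval 67.7 to 15079), and little at the promoter of Cd93 (chromosome 2, 148442489 to 148444489), with 0.624 ± 0.467 CPM against 26.6 ± 2.88.

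Other regions with the largest differences were higher in Kupffer cells near Csrp1 (6.67, SE 0.47), Phactr1 (6.64, SE 0.42), Agtr2 (6.62, SE 0.50), Ptprm (6.55, SE 0.33), Chp2 (6.29, SE 0.45), Ptgis (6.26, SE 0.39), Zfp281 (6.24, SE 0.41) and Spag9 (6.07, SE 0.36). In an intron region of Tcf7l1, with 3 tags in RLM, the ratio was 221 (95% interval 75.3 to 1072). Lower regions lay near Papss1 (-6.50, SE 0.38), Dennd4c (-5.63, SE 0.42), Myo5a (-5.54, SE 0.38), Zc3h12c (-5.37, SE 0.41), Runx3 (-5.33, SE 0.39) and Pqlc3 (-5.20, SE 0.38). The RLM to Kupffer cell ratio was 68.0 (22.8 to 334) near Xylt1 and 60.7 (20.3 to 298) near Plcb1, each with 3 tags in Kupffer cells.

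Of the 30 Kupffer cell identity genes 26 were higher in Kupffer cells than in RLM, 1 was lower (Arhgef37, -1.57, SE 0.22) and 3 did not pass (Clec2i -0.09, Cd207 -0.11, Cdh5 -0.16). The identity list had adjusted p = 2.07e-33, and adjusted p = 0.250 with an estimated correlation. Pcolce2 (4.74, SE 0.22) stood highest, followed by Clec4f, Paqr9 (4.56, SE 0.21) and Clec1b (4.11, SE 0.29). Among the 18 macrophage genes the mannose receptor gene Mrc1 (2.88, SE 0.18) and Adgre1 (1.86, SE 0.16) were higher while Cd63 (-3.09, SE 0.36) and Gpnmb (-2.60, SE 0.25) were lower. That list had 10 higher and 2 lower, with adjusted p = 7.72e-05, and adjusted p = 0.250 with an estimated correlation. Among the 22 LXR targets Apoc1 (4.09, SE 0.24), Pltp (1.73, SE 0.17) and Scd1 (1.69, SE 0.16) were higher and Abcg8 (-1.21, SE 0.40) was lower. This list had 10 higher and 1 lower, with adjusted p = 2.69e-06, and adjusted p = 0.250 with an estimated correlation. Iron and heme genes had 7 higher and 0 lower of 15, with the hemoglobin scavenger receptor gene Cd163 at 2.55 (SE 0.23) and Hmox1 at 1.25 (SE 0.15). For iron genes adjusted p = 0.000425, and adjusted p = 0.362 with an estimated correlation.

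Some genes of the inflammatory, interferon and class II lists were also higher in Kupffer cells than in RLM. The NF-kB list had 7 higher and 0 lower of 20, among them Il6 (2.81, SE 0.19), Il1a (2.28, SE 0.18) and Il10 (2.27, SE 0.17). For that response adjusted p = 9.29e-05, and adjusted p = 0.250 with an estimated correlation. The interferon list had 7 higher of 20, among them Ifit3 (1.90, SE 0.21) and Cxcl10 (1.64, SE 0.20). For interferon genes adjusted p = 0.000878, and adjusted p = 0.468 with an estimated correlation. Class II genes had 6 higher of 12, with the class II activator gene Ciita at 1.69 (SE 0.18). For class II genes adjusted p = 0.000183, and adjusted p = 0.362 with an estimated correlation. The TGF-beta and BMP targets (6 higher, 2 lower of 21, adjusted p = 0.0604) held Hpgd at 2.57 (SE 0.17) and Bambi at -1.19 (SE 0.26). Monocyte genes went both ways, with Fn1 (-4.84, SE 0.40) and Hp (-3.48, SE 0.38) lower and Ifitm6 (2.03, SE 0.19) and Plac8 (1.48, SE 0.15) higher. In all, 4 were higher and 8 lower of 19 (adjusted p = 0.0596). Notch targets had 3 higher and 2 lower of 18 (adjusted p = 0.985), with Hey1 at 2.00 (SE 0.18), Hes1 at 0.27 (SE 0.19), which did not pass. The median (-0.06) and mean (-0.12) of that list were below 0 where the test pointed up. The monocyte list was called without RLM replicate 1 (adjusted p = 0.00878) and the TGF-beta and BMP list without Kupffer cell replicate 2 (0.0269). Fry gave adjusted p = 0.0282 for monocyte genes (downward) and 0.00511 for TGF-beta and BMP targets (upward).

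Cell cycle genes had 3 higher and 1 lower of 20 (adjusted p = 0.594). By camera no marker list of another cell type was called. Hepatocyte genes had 2 higher and 2 lower of 9 (adjusted p 0.985), endothelial 4 and 4 of 12 (0.985) and stellate 2 and 3 of 8 (0.985). Neutrophil genes had 5 higher and 3 lower of 13 (0.508), lymphocyte 0 and 3 of 13 (0.220), dendritic cell 6 and 3 of 13 (0.121), and erythroid and megakaryocyte 0 and 2 of 6 (0.121). Fry gave adjusted p = 0.00224 for dendritic cell, 0.00725 for neutrophil and 0.0261 for cell cycle genes (upward), and 0.0160 for erythroid and megakaryocyte and 0.0282 for lymphocyte genes (downward). Endothelial Stab2 was higher in Kupffer cells by 2.47 (SE 0.21), and Tal1, of the erythroid list, was lower (-3.36, SE 0.25). Adjusted over the list alone, 5 endothelial and 4 stellate genes were lower and 2 lymphocyte genes, and the other counts were the same.

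Across 80982 tested regions, 18043 in 10996 loci were higher in Kupffer cells than in RLM and 11283 in 8563 loci were lower by the edgeR test. Distal regions, over 3 kb from a start, made up 78.2% of the higher and 72.4% of the lower. Without Kupffer cell replicate 2, the deepest of the 6 libraries, 5332 regions were lower, and DESeq2 called 7515 lower. Scaling by total tags moved the median log2 difference of all regions by -0.144 here and by -0.111 between Kupffer cells and monocytes. The share of calls that were higher in Kupffer cells than in RLM went from 61.5% to 54.7%. It called 0 of the regions in the opposite direction, which a move of that size could hardly do to a 2-fold call. RLM had been exposed to toxin and Kupffer cells had not, and the sample labels give the Kupffer cells another strain than RLM while the series text gives both the same, so toxin and perhaps strain differ with the cell type.

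**Figure D2:**
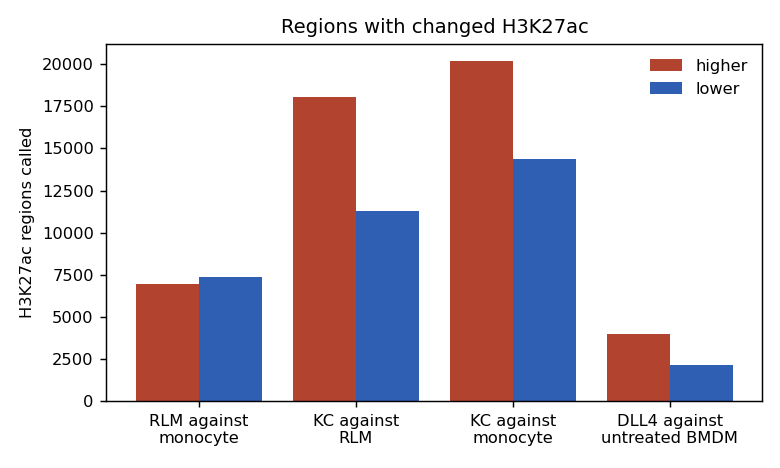
Number of H3K27ac regions higher and lower in each of the 4 comparisons (bars, count of regions at an adjusted p under 0.05 and at least 2-fold). The Kupffer cell against monocyte bars reach 20184 and 14353, and the DLL4 bars 4018 and 2164.

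The full distance from blood monocyte to Kupffer cell was measured with the same libraries. Kupffer cells had 68.7 ± 9.17 CPM at the C1qb promoter against 0.454 ± 0.176 in monocytes (log2 difference 7.21, SE 0.34), and 61.3 ± 10.8 against 0.413 ± 0.117 in an intron region of the leptin receptor gene Lepr (chromosome 4, 101741200 to 101743200). At the promoter of Fn1 (chromosome 1, 71652257 to 71654257), which encodes fibronectin, Kupffer cells had 0.178 ± 0.0857 CPM and monocytes 29.1 ± 6.46 (-7.42, SE 0.47). The F10 promoter held 1 tag in Kupffer cells and 1181 in monocytes, a ratio of 1241 (95% interval 222 to 49047).

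Further regions higher in Kupffer cells lay nearest to Sdc3 (7.56, SE 0.36), Ptprm (7.40, SE 0.37), Cdc42bpg (7.26, SE 0.44), Itga9 (7.15, SE 0.37), Arl15 (7.15, SE 0.48), Kcna2 (7.13, SE 0.48) and Oacyl (7.13, SE 0.40), and the ratio near Dusp1, with 3 monocyte tags, was 230.3 (78.5 to 1120). Regions lower in Kupffer cells lay nearest to Papss1 (-7.80, SE 0.37) and Arhgef10l (-7.04, SE 0.46). Where Kupffer cells held 3 tags, the ratios of monocyte to Kupffer cell tags were 228 (77.8 to 1110) near Bfsp1, 216 (73.6 to 1051) near Bri3bp, 191 (65.1 to 930.0) near Plcb1, 188 (64.1 to 916) near Xylt1 and 170.2 (57.9 to 828) near Pdlim1. Near Hp, with 2 tags, the ratio was 158 (43.4 to 1312).

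Kupffer cell identity genes had 27 higher and 1 lower of 30 against monocytes, with Clec4f at 5.53 (SE 0.22), Spic at 5.44 (SE 0.22) and Id3 at 3.26 (SE 0.16), while Folr2 (0.98, SE 0.24) and Cd207 (0.63, SE 0.43) did not pass. For this list adjusted p = 2.11e-41, and adjusted p = 0.108 with an estimated correlation. LXR targets had 17 higher and 0 lower of 22 (adjusted p = 1.58e-18, and adjusted p = 0.108 with an estimated correlation), with Abca1 at 4.11 (SE 0.17) and Apoc1 at 4.00 (SE 0.24). Macrophage genes had 13 higher and 1 lower of 18 (adjusted p = 1.23e-13, and adjusted p = 0.108 with an estimated correlation), with Mertk at 4.57 (SE 0.18) and Cd63 at -1.19 (SE 0.38). TGF-beta and BMP targets had 11 higher and 2 lower of 21 (adjusted p = 4.94e-05, and adjusted p = 0.110 with an estimated correlation), with Id2 at 3.98 (SE 0.18) and Skil at 1.77 (SE 0.15). Monocyte genes had 2 higher (Plac8, 1.53, SE 0.15, and Ccr2, 1.11, SE 0.21) and 11 lower of 19, led by Fn1 (-7.32, SE 0.36) and Hp (-5.09, SE 0.35). For monocyte genes adjusted p = 7.51e-06, and adjusted p = 0.117 with an estimated correlation.

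Iron and heme genes had 8 higher of 15 (Slc40a1, 4.40, SE 0.18; adjusted p = 1.71e-08, and adjusted p = 0.203 with an estimated correlation). The NF-kB list had 9 higher and 2 lower of 20 (Il10, 3.61, SE 0.18; adjusted p = 4.06e-05, and adjusted p = 0.117 with an estimated correlation). Interferon genes had 8 higher of 20 (Oasl1, 2.53, SE 0.16), with adjusted p = 0.00678 and adjusted p = 0.602 with an estimated correlation. Class II genes had 7 higher of 12 (H2-Eb1, 3.24, SE 0.26), with adjusted p = 6.15e-05 and adjusted p = 0.303 with an estimated correlation. Notch targets had 5 higher and 2 lower of 18, among them Hey1 (3.13, SE 0.19), Hes1 (2.97, SE 0.21) and Notch3 (-2.07, SE 0.64), with adjusted p = 0.119. Dendritic cell genes had 8 higher and 3 lower of 13 (adjusted p = 0.143), including Irf8 (2.47, SE 0.15) and Bcl11a (-3.74, SE 0.19). Both this list and the Notch list reached adjusted p = 0.0486 without Kupffer cell replicate 2. The hepatocyte (2 higher, 1 lower of 9), endothelial (4 and 4 of 12), stellate (2 and 1 of 8), neutrophil (4 and 5 of 13), erythroid (1 and 2 of 6) and cell cycle lists (5 and 2 of 20) had adjusted p = 0.953. The lymphocyte list (1 and 1 of 13) had 0.446. Where camera made no call, fry gave adjusted p = 0.00169 for Notch targets, 0.000854 for dendritic cell and 0.0407 for neutrophil genes, each upward. For the hepatocyte and endothelial lists the median was below 0 (-0.31 and -0.69) and the mean above it (0.26 and 0.01). The neutrophil list showed the reverse (0.14 and -0.08), and for the stellate list the median (-0.51) and mean (-0.10) were below 0 where the test pointed up. Adjusted over the list alone, 8 class II genes were higher, and the other counts were the same.

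By the edgeR test, 20184 regions in 12299 loci were higher in Kupffer cells than in monocytes and 14353 in 10210 loci were lower. Much of the difference seen in RLM was present in Kupffer cells. Of the 6942 regions higher in RLM than in monocytes, 5573 (80.3%) were also higher in Kupffer cells, where independent lists would share 1730, and 3152 of these were higher again in Kupffer cells than in RLM. Of the 7399 lower regions, 4512 (61.0%) were also lower in Kupffer cells against 1311 for independent lists. The other way, 648 regions higher in RLM (9.33%) were lower in Kupffer cells than in RLM, against 13.9% of all tested regions. Of those lower in RLM, 1702 (23.0%) were higher in Kupffer cells than in RLM, against 22.3% of all, and these comparisons share the RLM libraries. A further 14445 higher and 9755 lower regions were called in Kupffer cells alone of the pair. Both lists were made against the same monocyte libraries, which by itself correlates their log2 values (r = 0.483 in simulated counts without a difference, 0.587 observed, across regions, which are not independent replicates). The covariance of these values was 0.105 in the simulated counts and 0.996 observed, so the shared libraries gave only a small part of it. The 3 simulated draws held no call in either list, so they do not show how far the shared libraries raise the overlap.

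DLL4 in culture was used to ask which regions respond to a Notch ligand in macrophages without other liver signals. Hes1 was the only measured Notch target that rose over all its regions. Its promoter region (chromosome 16, 30064214 to 30066214) rose from 0.417 ± 0.178 to 15.8 ± 0.486 CPM (n = 2), and all its regions together from 8.44 ± 1.04 to 74.4 ± 4.79. An intron region of Itga9 (chromosome 9, 118611432 to 118613432), an integrin subunit, rose from 0.732 ± 0.347 to 13.2 ± 0.909 CPM. An intergenic region at -64900 bp from the start of Rbpj (chromosome 5, 53489879 to 53491879), which encodes the DNA-binding partner of Notch, fell from 21.5 ± 3.06 to 5.36 ± 0.446 CPM. Over all regions of Rbpj the log2 change was -0.83 (SE 0.06), under the 2-fold minimum.

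Regions near Apol10b (5.99, SE 0.42), Clic5 (5.77, SE 0.27), Apol7c (5.38, SE 0.37), Adgrl3 (4.72, SE 0.30), Fam50b (4.58, SE 0.25), Sash1 (4.57, SE 0.32), Mpp6 (4.50, SE 0.26) and Abcg3 (4.37, SE 0.27) also rose. The largest falls were near Vps13c (-2.69, SE 0.21), Prg4 (-2.31, SE 0.28), Rnf141 (-2.29, SE 0.17), Map3k20 (-2.14, SE 0.29), Btg3 (-2.10, SE 0.20), Lamc1 (-2.10, SE 0.29), Arhgap18 (-2.04, SE 0.26), Cacng6 (-2.02, SE 0.29) and Nadk (-2.02, SE 0.27).

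With DLL4, 8 of 28 measured Kupffer cell identity genes rose and 0 fell (adjusted p = 6.38e-06, and adjusted p = 0.153 with an estimated correlation). Cd38 rose by 1.72 (SE 0.12), from 17.7 ± 0.252 to 58.6 ± 2.84 CPM, and Spic (1.56, SE 0.33), Il18bp (1.54, SE 0.06), Slc40a1 (1.26, SE 0.04) and Nr1h3 (1.07, SE 0.10) rose with it. Clec4f (-1.23, SE 0.74) and Timd4 (-0.25, SE 0.43) did not pass. Class II genes had 5 risen of 12, including H2-Ab1 (2.02, SE 0.21) and Ciita (1.42, SE 0.09). Their adjusted p was 1.70e-05, with adjusted p = 0.153 with an estimated correlation. Of 18 macrophage genes 3 rose, the C1q subunits C1qa (1.47, SE 0.11), C1qc (1.24, SE 0.07) and C1qb (1.14, SE 0.07). For macrophage genes adjusted p = 9.61e-10, and adjusted p = 0.153 with an estimated correlation. Dendritic cell genes had 3 risen of 13 (Clec9a, 1.53, SE 0.07; Fscn1, 1.49, SE 0.12; Batf3, 1.01, SE 0.05). For dendritic cell genes adjusted p = 5.15e-06, and adjusted p = 0.153 with an estimated correlation.

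The LXR list was called although only Nr1h3 of 22 passed (adjusted p = 1.70e-05, and adjusted p = 0.153 with an estimated correlation). So was the TGF-beta and BMP list with only Hpgd of 21 (1.30, SE 0.08; adjusted p = 0.00805, and adjusted p = 0.246 with an estimated correlation). Cell cycle genes were called downward with 1 fallen of 20 (Ccne2, -1.09, SE 0.14; adjusted p = 0.000590, and adjusted p = 0.167 with an estimated correlation). Of 17 Notch targets only Hes1 rose, by 3.13 (SE 0.13). Their list was not called (adjusted p = 0.745), with a median of -0.06 and a mean of 0.10. The lists of iron genes (2 risen of 15, adjusted p = 0.0762), NF-kB (Il1b, 1.40, SE 0.09, risen and Ccl2, -1.52, SE 0.09, fallen of 20, 0.509), monocyte genes (1 risen, Cxcr4, and 1 fallen of 18, 0.509) and interferon genes (0 of 20, 0.703) were not called by camera either, while fry gave iron genes adjusted p = 0.0128 (upward). Nor were the hepatocyte (2 fallen of 5, 0.240), endothelial (1 risen of 11, 0.450), stellate (1 fallen of 8, 0.663), neutrophil (0 of 15, 0.351), lymphocyte (1 risen of 14, 0.351) and erythroid lists (0 of 6, 0.509). Adjusted over the list alone, 3 stellate genes fell, and the other counts were the same.

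Of 82089 regions tested by edgeR, 4018 in 2866 loci rose with DLL4 and 2164 in 1831 loci fell, 84.4% and 87.8% of them over 3 kb from a start against 67.4% of all tested. At any fold, 10354 rose and 7203 fell.

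The binding maps were compared to find where each factor sat in Kupffer cells and not in BMDM. At Clec4f, LXR had 4 reproducible Kupffer cell peaks and SMAD4 had 5, and no BMDM list of these factors had a reproducible peak nearest to this gene. The strongest SMAD4 peak there (chromosome 6, 83634073 to 83634251) had 236 ± 56.3 tags per 10 M (n = 2) and lay 426-fold over input. The median peak of these 2 SMAD4 lists held only 1 and 2 input tags, so such folds are imprecise. Timd4 had 12 LXR peaks in Kupffer cells, and Spic had 3, all absent from both BMDM lists. At Hes1, SMAD4 had 12 Kupffer cell peaks, 9 of them absent from both BMDM lists, and RBPJ had 5 in each cell type. A peak near Smad7 (chromosome 18, 75367097 to 75367275 in Kupffer cells), an inhibitor that SMAD signalling induces, was strong in both cell types, with 303 ± 19.2 tags in Kupffer cells and 331 ± 42.9 in BMDM.

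All 30 Kupffer cell identity genes were nearest to a reproducible LXR peak in Kupffer cells, 22 of them to a peak absent in BMDM, and 28 to a SMAD4 peak, 24 of them to one absent in BMDM. In BMDM 22 of these genes had an LXR peak and 16 a SMAD4 peak. Kupffer cell LXR peaks were common near other lists too, at 12 of 12 class II, 14 of 15 iron and 18 of 20 NF-kB genes. They were less common near monocyte (14 of 20) and lymphocyte genes (3 of 22). The share over all genes is not given here. Among LXR targets, 23 of 24 had an LXR peak in Kupffer cells and 21 in BMDM, where the peak at Mylip reached 1108 ± 193 tags and that at Abca1 764 ± 87.0. Among TGF-beta and BMP targets, 19 of 22 had a SMAD4 peak in Kupffer cells and 17 in BMDM. Of the 20 Notch targets, 6 had an RBPJ peak in Kupffer cells and 17 in BMDM.

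The strongest LXR peaks of Kupffer cells absent from both BMDM lists lay nearest to Paqr9 (257 ± 139 tags, chromosome 9, 95572606 to 95572826), Mroh2a (229 ± 156), Stk10 (173 ± 121), Mrpl3 (169 ± 87.0) and Lepr (169 ± 81.1). Those of BMDM given GW3965 lay nearest to Atf3 (623 ± 109), Ccr1 (367 ± 10.5), Ccdc90b (328 ± 65.8), Poc1a (247 ± 44.3) and Eea1 (242 ± 58.4). For SMAD4 the Kupffer cell genes were Skil (255 ± 86.1), Cltc (240.2 ± 64.1), Clec4f, St3gal4 (229.8 ± 17.7) and Sh2b3 (227 ± 103). Those of BMDM were Il21r (299 ± 58.0), Syngr1 (269 ± 110), Irak2 (261 ± 0.212), Tmem230 (254 ± 31.4) and Ppcdc (240.5 ± 141). RBPJ peaks were weak in Kupffer cell nuclei, at Ergic1 (27.1 ± 3.54), Cltc (20.4 ± 3.11), Cacng4 (18.6 ± 2.69), Tsn (17.1 ± 1.98) and Hif3a (15.7 ± 0.495). In BMDM they were strong, at Atp5d (311 ± 13.8), Atf3 (275 ± 2.26), Cd68 (266 ± 7.21), Prcc (256 ± 1.56) and Prc1 (253 ± 6.43).

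For LXR, 23112 peaks were reproducible in Kupffer cells and 20354 in BMDM, and 10580 Kupffer cell peaks (45.8%) overlapped one of BMDM. SMAD4 had 18593 and 16969, with 8137 shared (43.8%). RBPJ had 5444 in Kupffer cell nuclei and 62698 in BMDM, with 4573 shared, 84.0% of the Kupffer cell peaks and 7.30% of those of BMDM. Intervals shifted along the chromosomes shared at most 105, 79 and 71. Replicates of 1 cell type overlapped only in part. For LXR, 55.4% and 33.1% of the peaks of Kupffer cell replicates 1 and 2 met one of the other replicate. In BMDM 48.2% and 67.1% did. For SMAD4 the shares were 50.01% and 73.3% in Kupffer cell nuclei and 45.7% and 59.3% in BMDM. For RBPJ they were 40.6% and 48.3% in nuclei and 77.9% and 79.4% in BMDM. A peak found in 1 cell type alone is therefore not shown to be specific to it. An LXR peak overlapped 65.2% of SMAD4 peaks in Kupffer cells and 52.4% in BMDM, and an RBPJ peak overlapped 21.2% and 91.8%, shares that follow the length of the RBPJ lists and were not set against chance.

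These counts follow list length, so each library weighs on them. A peak counts for 1 cell type alone where it met no reproducible peak of the other. It may still meet a peak found in 1 replicate there. Absent from both lists of BMDM were 7351 LXR, 5337 SMAD4 and 406 RBPJ peaks of Kupffer cells. Absent from both Kupffer cell lists were 5163, 4817 and 48881 of BMDM. Peaks of Kupffer cells alone numbered 12532 for LXR, but 58296 without replicate 1 of that cell type and 27556 without replicate 2. Those of BMDM alone numbered 9772, but 6155 without Kupffer cell replicate 2 and 17864 and 28263 without BMDM replicate 1 or 2. SMAD4 peaks of Kupffer cells alone numbered 10456, but 16297 and 25842 without Kupffer cell replicate 1 or 2. Those of BMDM alone numbered 8833, but 5633 without Kupffer cell replicate 2 and 18733 and 25504 without BMDM replicate 1 or 2. RBPJ peaks of Kupffer cells alone numbered 871, but 3115 and 3202 without Kupffer cell replicate 1 or 2, with 8162 and 10192 shared. With equal numbers of peaks per list (11277), 35.8% of the RBPJ peaks of Kupffer cell nuclei were shared instead of 84.0%. Only 1.01% and 0.76% of RBPJ tags lay in peaks in Kupffer cell nuclei against 25.1% and 24.5% in BMDM. Nuclei against cells and, for LXR, agonist against none differ together with the cell type.

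**Figure D3:**
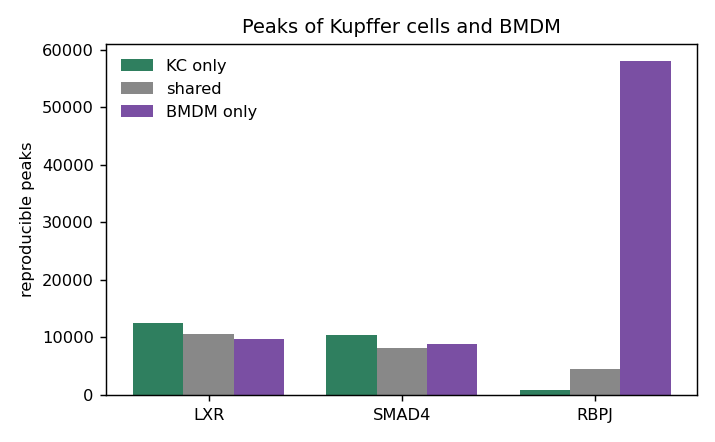
Number of reproducible peaks shared by Kupffer cells and BMDM, or overlapping no reproducible peak of the other, for LXR, SMAD4 and RBPJ (bars, count of peaks). RBPJ had 58122 peaks in BMDM that overlapped no reproducible peak of Kupffer cell nuclei.

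Factor peaks were then placed on the H3K27ac regions, to ask whether regions that differed held them more often. Kupffer cell LXR peaks lay in 61.4% of the regions higher in Kupffer cells than in RLM and in 32.1% of regions whose adjusted p exceeded 0.05, an odds ratio of 3.36 (95% interval 3.24 to 3.48). In the lower regions they lay in 11.5% (0.274, 0.258 to 0.292). Kupffer cell SMAD4 peaks had odds ratios of 2.58 (2.49 to 2.67) and 0.342 (0.322 to 0.364), and Kupffer cell RBPJ peaks 1.74 (1.65 to 1.83) and 0.374 (0.336 to 0.415). These regions were called on Kupffer cell acetylation, and the peaks were mapped in the same cell type. Peaks of any factor could follow acetylation there, so these odds ratios do not single out a factor. The same holds for Kupffer cells against monocytes. In regions higher in RLM than in monocytes, the odds ratios were 2.53 (2.41 to 2.66) for LXR, 2.18 (2.07 to 2.29) for SMAD4 and 1.60 (1.48 to 1.72) for RBPJ peaks of Kupffer cells. Regions lower in RLM held them more often too, with 1.47 (1.40 to 1.54), 1.61 (1.53 to 1.69) and 1.31 (1.21 to 1.41). In regions higher in Kupffer cells than in monocytes they were 3.27 (3.16 to 3.39), 2.39 (2.30 to 2.47) and 1.57 (1.49 to 1.66), and in the lower regions 0.600 (0.573 to 0.629), 0.696 (0.664 to 0.729) and 0.652 (0.603 to 0.705). Regions that rose with DLL4 held BMDM LXR peaks more often (2.17, 2.03 to 2.31), and BMDM SMAD4 (1.17, 1.09 to 1.26) and RBPJ peaks (1.27, 1.18 to 1.37) slightly more often. No factor was mapped in BMDM given DLL4. The SMAD4 and RBPJ peaks came from untreated BMDM and the LXR peaks from BMDM given GW3965, so binding under DLL4 was not measured. Regions that fell with DLL4 gave 1.10 (1.00 to 1.21) for LXR, 1.07 (0.968 to 1.18, adjusted p = 0.199) for SMAD4 and 1.80 (1.62 to 2.01) for RBPJ peaks of BMDM. With equal list lengths RBPJ gave 1.12 in risen and 1.02 in fallen regions. Kupffer cell peaks of LXR, SMAD4 and RBPJ had 1.86, 1.66 and 1.62 in risen and 0.339, 0.292 and 0.345 in fallen regions.

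The tests were repeated within strata of mean count over all libraries of a table, which include the groups compared. Within a stratum the level can still differ in the cell type where the peaks were mapped. The strata therefore adjust for level only in part. Within strata of mean count the odds ratio of Kupffer cell LXR peaks fell to 1.71 in regions higher in Kupffer cells than in RLM and to 1.25 in regions higher in RLM than in monocytes. SMAD4 peaks of Kupffer cells then gave 1.29 and 1.02 (adjusted p = 0.554 for the second), and RBPJ peaks 1.10 and 0.937 (adjusted p = 0.101 for the second). In regions higher in Kupffer cells than in monocytes LXR gave 1.58, SMAD4 1.15 and RBPJ 0.956 (adjusted p = 0.137). For the step from monocyte to RLM neither SMAD4 nor RBPJ peaks of Kupffer cells were above 1 by the test within strata. Peaks of BMDM gave 1.54 for LXR, 1.14 for SMAD4 (Mantel-Haenszel adjusted p = 3.54e-06) and 0.787 for RBPJ in the regions higher in RLM. In regions lower in RLM the strata gave 0.653 for LXR, 0.724 for SMAD4 and 0.783 for RBPJ peaks of Kupffer cells. Peaks of BMDM gave 1.32, 1.22 and 1.58 there, so their excess was not particular to regions higher in RLM. Without strata, BMDM peaks gave 2.47, 1.93 and 1.27 in regions higher and 2.21, 2.07 and 2.53 in regions lower in RLM. For regions risen with DLL4 the strata gave 1.86 for LXR, 0.976 for SMAD4 (adjusted p = 0.553) and 0.914 for RBPJ peaks of BMDM (adjusted p = 0.0268), and for fallen regions 1.24, 1.37 and 1.78. Kupffer cell peaks gave 1.59, 1.45 and 1.502 in risen and 0.384, 0.351 and 0.469 in fallen regions. Among regions over 3 kb from a start, without strata, the Kupffer cell odds ratios of LXR, SMAD4 and RBPJ were instead larger: 3.64, 3.11 and 2.21 in regions higher in RLM, 5.75, 4.94 and 2.96 in those higher in Kupffer cells than in RLM, and 5.27, 3.91 and 2.30 against monocytes. All are two-sided Fisher's exact or Mantel-Haenszel tests over regions that overlap, so the intervals are too narrow.

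**Figure D4:**
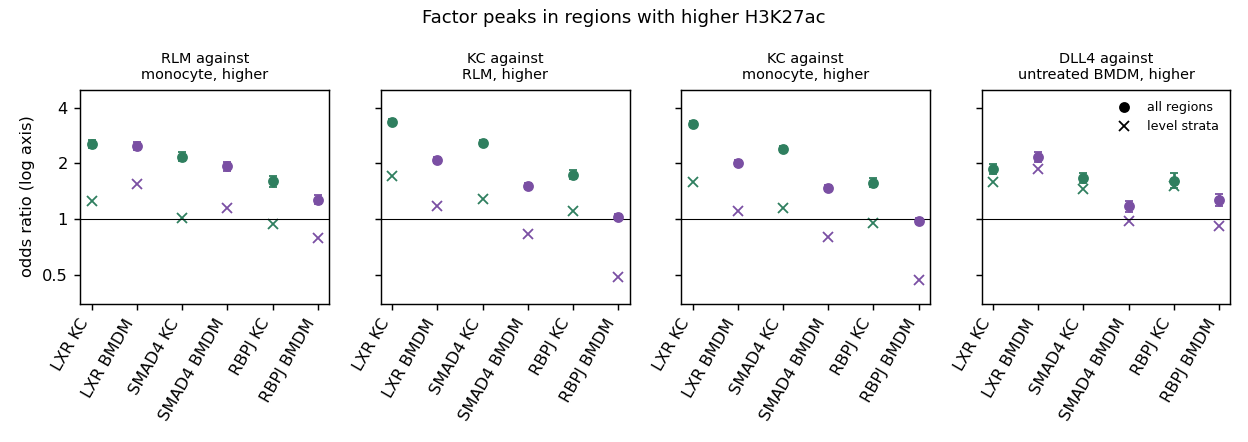
Odds ratio (log axis) of holding a factor peak in regions with higher H3K27ac against regions whose adjusted p exceeded 0.05, for 6 peak sets in 4 comparisons. Circles are all regions with 95% intervals and crosses the value within strata of mean count, with peaks of Kupffer cells in green and of BMDM in purple.

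Finally the response to DLL4 was matched to the difference between RLM and monocytes over 67006 regions present in both tables. Regions with both a rise under DLL4 and a higher level in RLM included ones of Hes1 (chromosome 16, 30066144 to 30068144, log2 values 5.14 and 3.49), Cd38 (2.67 and 2.78), Itga9 (4.11 and 4.48) and Csf1r (2.84 and 2.61), the receptor of a macrophage growth factor. These 4 genes were chosen after their values were seen. Of the 3475 matched regions that rose with DLL4, 745 (21.4%) were higher in RLM, against 8.52% of the rest (odds ratio 2.93, 2.69 to 3.19), and 280 were lower in RLM (0.759, 0.670 to 0.860). Of the 1448 that fell, 357 were lower in RLM (2.97, 2.63 to 3.36) and 48 higher (0.334, 0.250 to 0.446). The other regions of the 6155 higher in RLM did not pass as risen with DLL4, and over all matched regions the log2 values were weakly correlated (Pearson r 0.145, Spearman rho 0.122, across regions, which are not independent replicates). For the difference between Kupffer cells and monocytes, 1802 of the regions risen with DLL4 were higher in Kupffer cells (3.52, 3.29 to 3.77), and 1540 were higher in Kupffer cells than in RLM (2.97, 2.77 to 3.18). Adjusted p by two-sided Fisher's exact test was 8.82e-112 for the first overlap and 9.34e-06 for the odds ratio of 0.759 among regions lower in RLM. Regions that overlap in the same direction stayed in the comparisons of opposite direction. This by itself lowers the odds ratios of opposite direction, so they overstate any depletion. The tables share no library, but the starting cells differ, a blood monocyte in one and a cultured macrophage in the other.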

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

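Among the alternatives, 1 region per locus, thinned libraries and strata of level for the DLL4 overlap were tests chosen only after the data were seen. The rest were fixed beforehand, and each of those was run. Of the main results 291 values kept their direction and side of the threshold or stayed within 1.5 times, 45 moved, 1 weakened and 4 reversed. Of the single regions and lists and the other odds ratios, 1940 were the same, 34 weaker, 21 stronger and 16 reversed. No called region was called in the opposite direction under another scaling, count filter or fit. Calls need at least a 2-fold difference, so this does not show that no log2 value changed sign.

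With 1 region per locus, which tests fewer regions, RLM against monocyte gave 3362 higher and 4139 lower, Kupffer cells against RLM 10988 and 6304, Kupffer cells against monocyte 12051 and 8233, and DLL4 2606 and 1364. A mean of at least 50 tags, which also tests fewer, gave 9871 and 5646 for Kupffer cells against RLM and 11398 and 8375 against monocytes. DESeq2 gave 7515 lower in Kupffer cells against RLM, and the cause was not tested. At any fold, which drops a criterion, DLL4 gave 10354 and 7203, and 7047 regions were lower than in monocytes in both RLM and Kupffer cells. With an estimated correlation 0 lists were called by camera in each of the 4 comparisons, against 7 called at the preset correlation for RLM, 7 for Kupffer cells against RLM, 9 against monocytes and 7 for DLL4.

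With 1 library left out, its group has 1 library, assumed to vary like the others. Region counts then ran from 5724 to 6951 higher and 6419 to 8251 lower for RLM against monocyte, 14017 to 18705 and 5332 to 11910 for Kupffer cells against RLM, 17150 to 20654 and 10543 to 14602 against monocytes, and 3671 to 4251 and 1664 to 2236 for DLL4. The 5332 came without Kupffer cell replicate 2, the deepest library of its table, against 11283 with it. Lists called ran from 7 to 8, 7 to 8, 9 to 11 and 7 to 7 in the same order. Thinned to 7 M tags each, the libraries gave 6487 and 6909, 15768 and 10390, 18336 and 13938, and 3452 and 1798. Each count stayed within 1.5 times of the main one. The RLM libraries held only 7.37 and 9.47 M tags before thinning, so this does not show what more depth would add. Peaks ran from 11528 to 14199 shared, 9151 to 58296 in Kupffer cells alone and 6155 to 28263 in BMDM alone for LXR. For SMAD4 they ran from 9072 to 11598, 6995 to 25842 and 5633 to 25504, and for RBPJ from 4766 to 10192, 604 to 3202 and 52506 to 75637, since a single list takes the place of the reproducible set. LXR peaks in Kupffer cells alone numbered 58296 and 27556 without Kupffer cell replicate 1 or 2, and peaks in BMDM alone 17864 and 28263 without BMDM replicate 1 or 2, and 6155 without Kupffer cell replicate 2. The same 5 omissions gave 16297, 25842, 18733, 25504 and 5633 for SMAD4. RBPJ had 8162 shared and 3115 in Kupffer cells alone without Kupffer cell replicate 1, and 10192 and 3202 without replicate 2.

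Peaks at least 8-fold over input, which are fewer, gave 5568 shared and 6185 in BMDM alone for LXR, 4909 and 4974 for SMAD4, and 299 shared, 219 in Kupffer cells alone and 35407 in BMDM alone for RBPJ. Equal list lengths gave 1865, 3342 and 7769 for RBPJ, because the BMDM lists were shortened.

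Strata of mean count lowered the odds ratio of Kupffer cell peaks in regions higher in RLM to 1.02 for SMAD4 and 0.937 for RBPJ, and of RBPJ in regions higher in Kupffer cells than in monocytes to 0.956. In regions risen with DLL4 they gave 0.976 for SMAD4 and 0.914 for RBPJ peaks of BMDM. Other values turned by the strata were 0.787 for BMDM RBPJ peaks in RLM-higher regions, and 0.653, 0.724 and 0.783 for Kupffer cell LXR, SMAD4 and RBPJ peaks in RLM-lower regions. Regions higher in Kupffer cells gave 0.833 (against RLM) and 0.799 (against monocytes) for BMDM SMAD4 peaks, and 0.487 (against RLM) for BMDM RBPJ peaks. Regions lower in Kupffer cells than in monocytes gave 0.818, 0.815 and 0.843 for BMDM LXR, SMAD4 and RBPJ peaks, and 0.982 for RBPJ with equal list lengths. BMDM RBPJ peaks in regions higher in Kupffer cells, near 1 at first, gave 0.920 and 0.913 without BMDM replicate 1 or 2 (against RLM), but 1.26 in regions over 3 kb from a start, 1.18 with 1 region per locus and 1.82 with equal list lengths. Against monocytes these last 3 settings gave 1.13, 1.10 and 1.58. For the reversed odds ratios the cause was not tested.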

Other observations

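The tests of the RLM pattern and that of the 8-fold RBPJ peaks were chosen only after the result was seen, and the strata of level for DLL4 after the data were seen but before that overlap was computed. The other tests here were written before their results. Of the dendritic cell genes, Xcr1, a chemokine receptor, was lower in RLM than in monocytes (-1.35, SE 0.25) and higher in Kupffer cells than in RLM (2.36, SE 0.25), with 2 libraries per group. Flt3, a cytokine receptor of progenitors and dendritic cells, was lower at both steps (-1.79, SE 0.21, and -1.45, SE 0.23). Of the LXR peaks, 52.4% met a SMAD4 peak in Kupffer cells and 43.7% in BMDM, shares that were not set against chance.

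Regions higher in RLM than in monocytes might come from Kupffer cells left in the liver after toxin, or from weaker enrichment in the RLM libraries. A single admixed share would bring every region the same fraction of the way from monocyte to Kupffer cell, but over 3313 well covered regions that fraction had a 10th percentile of 0.00611 and a median of 0.101, which argues against residual Kupffer cells as the whole cause. The limits for these regions (at least 400 Kupffer cell tags and 8-fold over monocytes) replaced a first look at 100 tags and 4-fold, whose 10th percentile was -0.00723 (median 0.118). A small share of them stays open. Weaker enrichment stays open too, since these regions were selected for a high RLM level and their median of 6.50 CPM (1.82 in monocytes, 2.88 in RLM over all regions) decides nothing, and strain and toxin stay open, which the design does not separate from arrival in the liver.

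RBPJ had far fewer peaks in Kupffer cell nuclei than in BMDM. If lower enrichment only thinned 1 list of sites, few Kupffer cell peaks should be absent from BMDM. Of them, 7.46% were absent from both BMDM lists, as predicted. Those lists held 80480 and 78976 peaks against 13394 and 11277 of Kupffer cell nuclei. Their length alone could keep the absent share small, so it does not decide for thinning. Of the 518 Kupffer cell peaks at least 8-fold over input, 9.07% were absent from both full BMDM lists. Only 57.7% were shared when the BMDM peaks also had to reach 8-fold, and 35.8% of all with equal list lengths, settings that remove weaker BMDM peaks. A list thinned to its strongest sites should keep many of them under these settings. The share that thinning would give was not worked out, so the question stays open. Satellite or unplaced sequence held 0.0184% of the reproducible Kupffer cell peaks. The filter against input had already removed 22086 of 38285 and 23838 of 37496 putative peaks, which could include repeats. The share of reads from such sequence was not measured for these libraries, so this value does not decide about reads from repeats. A biological difference in RBPJ binding stays open and untested beside the lower enrichment, and nuclei and cells were also prepared differently.

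Regions that rose with DLL4 were found more often among regions higher in RLM, which may reflect a Notch response, a hypothesis that no test here addressed. The odds ratio was 2.97 among regions higher in Kupffer cells than in RLM and 3.52 among those higher than in monocytes, so the overlap is not particular to newly arrived cells. Enhancers that vary in any comparison would be enriched among RLM-lower regions too, and there the odds ratio was 0.759. The regions higher in RLM stayed in that comparison, and their overlap by itself lowers this value. It therefore shows no enrichment but does not by itself show a depletion. Regions of high signal could give an overlap by level, but within strata of level in both tables the odds ratio was 2.79. Both explanations are argued against, while other signals that act on the same enhancers were not tested.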
